A study of Homo sapiens with 24 samples.

How the data were processed

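TT-seq libraries of DLD1 cells were taken as deposited, 24 libraries in 12 groups of 2. Groups, times and replicate numbers came from the labels; the treatment protocol gives 3 h of dTAG13 for all, and the times in the titles and characteristics were used instead. Per the submitters' processing notes, Trim Galore 0.6.6, STAR 2.7.5c, SAMtools 1.9, Picard 2.23.3 and DESeq2 1.26.0 were used and the builds hg19 and mm10 were named, with no role given for either. Per the labels' protocols the libraries came from a stranded kit; whether counting used strand is not given in the sources used here, so genes that overlap others, and ribosomal protein genes with processed pseudogenes, are uncertain.

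Per the file headers the deposited values are FPKM, and the tests were chosen for FPKM before the data were examined. The deposited values instead behave as a signal per kilobase of gene. In batch 1 each was a whole number divided by the gene's length. A library factor applied before rounding to whole numbers would not be seen there. In batch 2 each was a whole number divided by the length and multiplied by 1 factor per library, 0.565 to 0.753. Lengths were found for 6828 of 6832 genes (median 33636.5 bp, so they hold introns), within a tolerance of 0.02 units; 100% of batch 1 values checked came out whole, as did 96.2 to 97.1% in batch 2. How the authors derived the factors is not given in the sources used here. In batch 1 the genes in the lowest of 5 bins by level differed between replicates by 0.77 to 1.00 of the variance that counting alone gives (0.95 to 1.06 in batch 2), so these numbers are called whole-number units and not reads. Count tests were therefore not used, and the log-scale test was kept.

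Batches were fitted apart. Genes with a mean value of at least 0.1 over the 12 libraries of a batch were tested, 6579 in batch 1 and 6950 in batch 2. Log2(value + 0.1) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, a trended and robust empirical Bayes spread shared by the batch, and Benjamini-Hochberg adjustment at 0.05 within each of 14 contrasts. Fold changes are on that scale, which understates changes of low genes. All p-values for genes are two-sided adjusted p-values from limma. The median SE of a log2 fold change was 0.09 in batch 1 and 0.06 in batch 2. Of 29 gene lists fixed before the data were examined, the 24 with at least 5 tested members were tested with limma's camera, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 24. Symbols were used as the files give them, and 7169 of 7223 matched the symbol table.

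Named genes were set by a rule made before the data were examined. For each of the 5 main 3 h contrasts it took the 6 called genes with the largest rise and the 6 with the largest fall, with a mean of at least 1 and both treated libraries on the same side of both controls, leaving out names of non-coding and uncharacterised loci. It also took the 2 called members of each list with the largest change, plus INTS11, INTS8 and PPP2CA. The same genes were read in the other contrasts, and the text gives a part of them.

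The procedure was tested on simulated data. For the INTS11 3 h contrast of batch 1, with 200 of 6579 genes changed, it recovered 20 of 50 genes changed 1.25-fold, 47 of 50 changed 1.5-fold and 48 of 50 changed 2-fold, with 9 false calls. Alternatives fixed before the data were examined were pseudocounts of 0.01 and 1, no filter and a filter at a mean of 1, centring each library on its median, a replicate block, only the libraries a contrast names, both batches in 1 fit, and each library left out in turn. Leaving 1 library out leaves a group of 1, which is assumed to vary like the other groups. Voom on the whole-number units, and averaging of pairs that agree within sampling noise, were added after seeing the data, as was a correction of each library for its loess trend with log2 gene length in the 2 contrasts of the N211del and INTS8 lines. Scripts ran in Python with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.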

Results

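Newly made RNA was measured by TT-seq, in which cells take up a uridine analogue for a short time and the labelled RNA is isolated and sequenced. The cells were DLD1, a human colorectal adenocarcinoma line, in which a subunit of Integrator carried a degron tag at its own gene, so that dTAG13, a small molecule, directs the tagged protein to degradation. Integrator acts on RNA polymerase II near promoters and joins an RNA endonuclease, whose catalytic subunit is INTS11, to the phosphatase PP2A, which INTS8 helps to hold. The series asks how the endonuclease and phosphatase parts differ in their roles in transcription. The 3 lines were INTS11-dTAG, INTS8-dTAG, and INTS8-dTAG with an added INTS8 variant that the labels call N211del. Batch 1 held each line after 3 h of dTAG13 or of the vehicle DMSO, and batch 2 held the INTS11 and N211del lines at 0, 1 and 3 h of dTAG13. Each of the 12 groups had 2 libraries, 24 in all. The listed genes held 5517104 to 8119831 whole-number units per library in batch 1 and 8709475 to 11266991 in batch 2. The median gene held 431 to 579.5 units in batch 1 and 617 to 842.5 in batch 2. INTS11, INTS8 and the PP2A catalytic gene PPP2CA were not analysed here. The tag acts on protein, so the loss of the tagged proteins could not be checked from RNA values. No untagged line was given dTAG13, so effects of dTAG13 itself are not set apart. Batch 2 had no vehicle group, so effects of vehicle, handling and time are not set apart there either. Replicate pairs correlated across genes at r = 0.9945 to 0.9965, and 6 of the 12 pairs differed by no more than counting noise (chi-square per gene 0.88 to 1.02). Batch 1 held 3 of these pairs, and scaling its units down before rounding would lower their chi-square. Agreement with counting noise, and the averaging that uses it, is therefore uncertain in batch 1. The labels call the pairs biological duplicates, so n = 2 was kept, but p-values measure only the spread between these libraries, which may be technical.

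In the INTS11 line 3 h of dTAG13 raised transcription of SOCS1, NR4A2 and HEXIM1 and lowered that of EGR1, CEP20 and LIN9. In batch 1 SOCS1, an inhibitor of cytokine signalling, rose from 2.62 ± 0.412 to 28.2 ± 3.71 (mean ± SD, n = 2; log2 fold change 3.38 ± 0.15 SE, adjusted p = 3.51e-08). NR4A2, an orphan nuclear receptor, rose from 3.87 to 22.3 ± 0.599 (log2 fold change 2.50 ± 0.08, adjusted p = 2.13e-15), and the muscle enolase ENO3 rose by a log2 fold change of 2.53 ± 0.13 (adjusted p = 4.71e-09). HEXIM1, the inhibitor of the elongation kinase P-TEFb, rose from 98.2 ± 4.29 to 193 ± 0.78 (log2 fold change 0.97 ± 0.07, adjusted p = 4.49e-10). Among the genes that fell most were EGR1, an immediate early transcription factor (log2 fold change −1.04 ± 0.13, adjusted p = 0.000288), the centrosomal gene CEP20 (−0.96 ± 0.09, adjusted p = 3.51e-08) and LIN9, a subunit of a cell cycle repressor complex (−0.96 ± 0.08, adjusted p = 9.31e-09).

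By group, 13 of 29 immediate early genes were higher and 4 lower after dTAG13 in the INTS11 line (16 and 5 adjusted over the list alone), with a list median of 0.22. Of 13 cholesterol synthesis genes, 9 were higher (9 adjusted over the list alone), such as the mevalonate enzyme PMVK (log2 fold change 0.88). Of 13 Wnt target genes, 9 were higher and 2 lower (9 and 2 adjusted over the list alone), among them the receptor EPHB3 (log2 fold change 0.90). Ribosomal protein genes went down, with 22 of 32 lower (24 adjusted over the list alone) and RPL22L1 at a log2 fold change of −0.66. Respiratory chain genes were lower for 19 of 39 members (20 adjusted over the list alone), such as the complex I gene NDUFS4 (log2 fold change −0.70). Proteasome genes were lower for 15 of 24 (15 adjusted over the list alone), with PSMC6 at −0.69, and spliceosome genes for 11 of 21 (13 adjusted over the list alone), with SF3B1 at −0.40. Limma's camera with a preset correlation placed these lists apart from other genes (adjusted p = 0.00817 for immediate early, 0.000448 for cholesterol synthesis, 0.0104 for Wnt target, 4.36e-05 for ribosomal protein, 6.63e-05 for respiratory chain, 0.000167 for proteasome and 0.000448 for spliceosome genes). Each lost that call with an estimated correlation (adjusted p = 0.594 with an estimated correlation for each). Fold changes here also ran with level (rho = −0.38), from a median of 0.24 in the lowest of 4 bins to −0.12 in the highest. No list was corrected for level, so this trend is not set apart from the list results. Cleavage and termination factors were lower for 8 of 14 and higher for 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0104, and adjusted p = 0.594 with an estimated correlation). The scaffold SYMPK fell (log2 fold change −0.71 ± 0.08), while ZC3H4, which restricts transcription outside genes, rose (0.81 ± 0.07). Of 6 Integrator subunit genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone), with a list median of −0.06 (camera adjusted p = 0.627). Among them NABP1 and INTS2 rose by log2 fold changes of 0.79 and 0.60.

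In all, 2575 of 6579 genes differed in batch 1, 1275 higher and 1300 lower, of which 550 rose and 79 fell by at least 1.5-fold. The count was 1686 (973 higher and 713 lower) without INTS11 dTAG13 replicate 2 and 3952 with both batches in 1 fit. It was 1374 (888 higher and 486 lower) with the pairs that agree within sampling noise averaged to 1 sample. The fit of both batches tested their mean response, against DMSO in batch 1 and 0 h in batch 2. Its 3952 is therefore not a count for batch 1 alone. Lower genes numbered 750 without INTS11 DMSO replicate 2, so the near-equal split rests on single libraries. In batch 2 the 3 h comparison was with 0 h, and CEP20 fell from 28.2 to 11.4 ± 0.221 (n = 2; log2 fold change −1.30 ± 0.05, adjusted p = 6.92e-07). MICU2, a regulator of mitochondrial calcium uptake, and PCNP fell by log2 fold changes of −1.04 and −1.03. SOCS1 rose by 2.84 ± 0.10 (adjusted p = 5.75e-07), the AP-1 gene FOSB by 2.30 ± 0.11 (adjusted p = 9.67e-07), HEXIM1 by 0.78 ± 0.03 and ZC3H4 by 1.23 ± 0.06 (log2 fold changes). Immediate early genes were higher for 19 of 31 and lower for 5 (19 and 5 adjusted over the list alone), and ribosomal protein genes higher for 2 and lower for 16 of 32 (2 and 16 adjusted over the list alone). Their camera adjusted p-values were 0.0378 and 0.00162, and neither call held (adjusted p = 0.653 with an estimated correlation for both). Fold changes here ran with gene length (rho = −0.284), from a median of 0.22 in the shortest of 4 bins to −0.02 in the longest. The immediate early median was 0.23, and no correction for length was made in this comparison. Cholesterol synthesis genes, called in batch 1, were not called in batch 2, with 5 of 13 higher and 3 lower (6 and 3 adjusted over the list alone; 4 and 4 with each library centred; camera adjusted p = 0.897). Nor were Wnt target genes, with 9 of 14 higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.0972). Of 6950 genes, 3847 differed, 2503 higher and 1344 lower, against 2207 and 2009 with each library centred on its median. The count was 2265 (1615 higher and 650 lower) with the pairs that agree within sampling noise averaged.

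In the INTS8 line dTAG13 raised FOSB, DIO3 and NDRG1, and lowered HOXB2 and PRR15L. FOSB rose from 1.11 ± 0.197 to 38.6 ± 3.54 (n = 2; log2 fold change 5.00 ± 0.13, adjusted p = 3.12e-18), and DIO3, which inactivates thyroid hormone, from 2.81 ± 0.361 to 91.2 ± 19.1 (4.96 ± 0.12, adjusted p = 2.82e-14). NDRG1, a hypoxia-induced gene, rose from 2.98 ± 0.141 to 35.3 ± 0.518 (log2 fold change 3.52 ± 0.10, adjusted p = 8.75e-18). HEXIM1 rose from 123 ± 3.12 to 349 ± 9.95 (2.83-fold, adjusted p = 1.15e-14). Genes that fell included the homeobox gene HOXB2 (28 ± 3.28 to 4.64 ± 0.596; log2 fold change −2.57 ± 0.19, adjusted p = 3.62e-06), TMEM45B (−2.77 ± 0.16, adjusted p = 2.59e-09), PRR15L (−2.20 ± 0.08, adjusted p = 2.72e-16) and the potassium channel gene KCNJ11 (−2.24 ± 0.27).

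Of 29 immediate early genes, 24 rose and 2 fell after dTAG13 in the INTS8 line (24 and 2 adjusted over the list alone), with a median log2 fold change of 1.01, while EGR1 fell (−0.83). Hypoxia and glycolysis genes rose for 10 of 16 and fell for 1 (10 and 1 adjusted over the list alone; 10 and 4 with each library centred), with the vasodilator gene ADM at 2.19. Interferon-stimulated genes rose for 10 of 15 (11 adjusted over the list alone), with OASL at 2.50 and IFI6 at 1.98. TGF-beta and BMP target genes rose for 7 of 8 (7 adjusted over the list alone, and 4 with each library centred), with a list median of 0.28. Among them were the inhibitory SMAD6 at 3.78 and SNAI1, a regulator of epithelial-mesenchymal transition, at 2.80. Ribosomal protein genes were lower for 24 of 32 (26 adjusted over the list alone), with RPL22L1 at −0.78, and spliceosome genes for 12 of 21 (12 adjusted over the list alone), with the splicing factor SRSF3 at −0.53. The camera adjusted p-values were 9.81e-07 for immediate early, 0.0141 for hypoxia, 0.0141 for interferon-stimulated, 0.0204 for TGF-beta, 9.81e-07 for ribosomal protein and 0.00212 for spliceosome genes. Each lost its call (adjusted p = 0.783 with an estimated correlation for each). In total 3656 genes differed, 2277 higher and 1379 lower, against 2017 and 2398 with each library centred on its median, and 1128 rose and 249 fell by at least 1.5-fold. Lower genes numbered 904 without INTS8 dTAG13 replicate 2 (2188 higher) and 836 with pairs averaged (1799 higher).

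In the N211del line dTAG13 raised FOSB, DIO3 and NDRG1 and lowered DAP, a gene linked to cell death, in both batches. FOSB rose to 26.1 ± 1.87 in batch 1 (n = 2; log2 fold change 3.49 ± 0.13, adjusted p = 2.12e-15) and from 1.61 ± 0.336 to 21.9 ± 0.256 in batch 2 (3.70 ± 0.11, adjusted p = 7.2e-09). DIO3 rose by 4.44 ± 0.12 and 4.03 ± 0.46, and NDRG1 by 2.65 ± 0.10 and 3.46 ± 0.06 (log2 fold changes in batch 1 and batch 2). HEXIM1 rose from 133 ± 2.41 to 382 ± 4.12 in batch 2 (log2 fold change 1.53 ± 0.03, adjusted p = 6.95e-10). DAP fell from 30.9 ± 0.344 to 10.3 ± 0.582 there (log2 fold change −1.58 ± 0.04, adjusted p = 3.85e-09) and by −1.45 ± 0.09 in batch 1 (adjusted p = 4.31e-12). The kinase gene STK39 fell in batch 2 (log2 fold change −1.57 ± 0.05, adjusted p = 8.67e-09), and HOXB2 in batch 1 (−2.22 ± 0.19, adjusted p = 1.01e-05). MAFA was listed at 0 in both 0 h libraries of batch 2 and at 4.51 and 3.72 in the 3 h libraries.

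The median gene was higher with dTAG13 in these libraries, by log2 fold changes of 0.21 in batch 1 and 0.18 in batch 2, so list medians are given relative to it. The batch 1 value was 0.14 without N211del dTAG13 replicate 2 and 0.29 without replicate 1. Whether batch 1 values were scaled for the library before rounding is not known, so this shift is not set apart from depth. Immediate early genes lay 0.48 above the median gene in batch 1 and 0.55 in batch 2, with 22 of 29 higher and 2 lower (22 and 2 adjusted over the list alone) and 25 of 31 higher and 3 lower (25 and 5 adjusted over the list alone). Hypoxia genes lay 0.36 and 0.50 above it, with 13 of 16 higher in batch 1 (14 adjusted over the list alone) and 14 of 16 in batch 2 (14 adjusted over the list alone), among them the glycolysis regulator PFKFB3 at a log2 fold change of 2.10 in batch 1. Ribosomal protein genes lay −0.27 and −0.26 from the median gene, with 1 higher and 4 lower of 32 in batch 1 (1 and 3 adjusted over the list alone) and 1 and 14 in batch 2 (1 and 13 adjusted over the list alone). With each library centred on its median, 30 and 31 of the 32 were lower. Centring left immediate early genes with 19 higher and 5 lower in batch 1 and 22 and 6 in batch 2, and hypoxia genes with 9 and 1 and with 10 and 4. Camera adjusted p-values in batch 1 and batch 2 were 0.00279 and 0.0102 for immediate early genes, 0.0167 and 0.0073 for hypoxia genes, and 1.41e-05 and 4.03e-06 for ribosomal protein genes. Each lost its call (adjusted p = 0.732 in batch 1 and adjusted p = 0.5 in batch 2 with an estimated correlation). In batch 1, 3191 genes were higher and 467 lower, against 1771 and 2316 with each library centred on its median, and lower genes numbered 263 with pairs averaged. In batch 2, 3454 were higher and 956 lower, against 2148 and 2436 with centring.

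**Figure D1:**
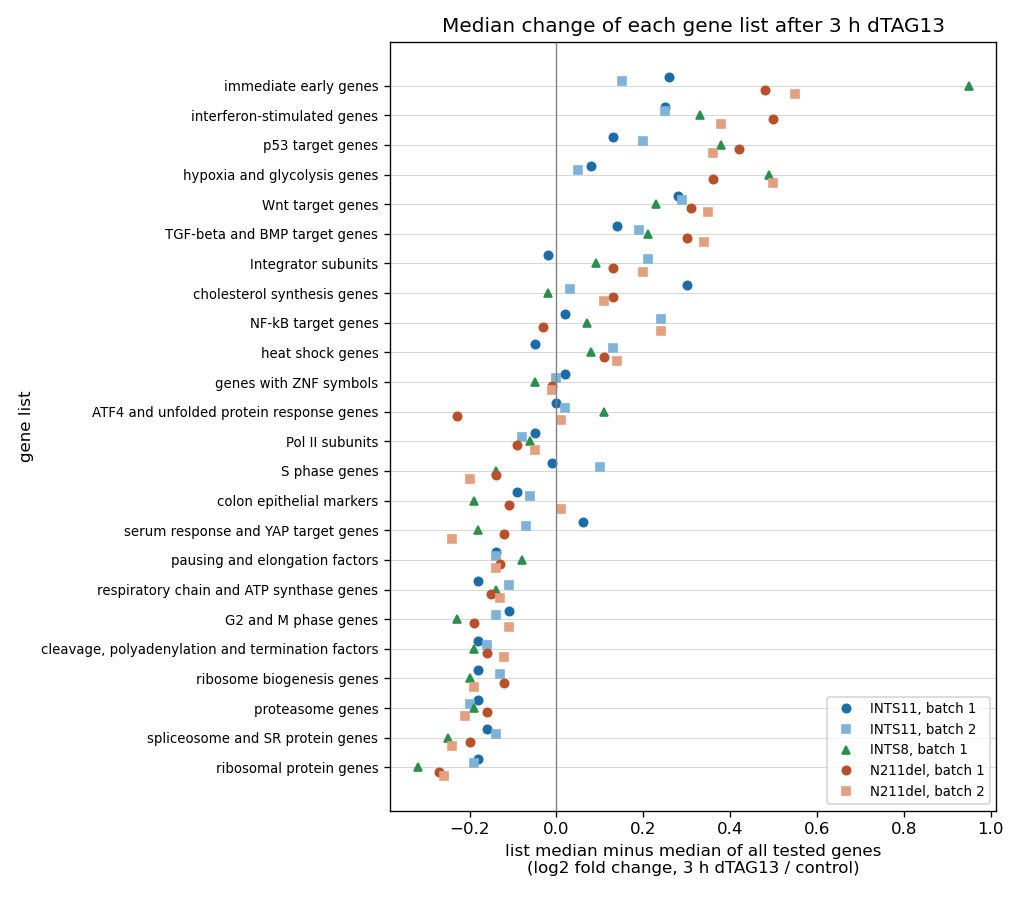
Each point is the median log2 fold change (3 h dTAG13 over control) of 1 gene list minus the median of all tested genes, on the horizontal axis, with lists down the side and 1 symbol for each of the 5 comparisons. Immediate early genes lie at 0.15 to 0.95 and ribosomal protein genes at −0.32 to −0.18.

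Changes of many single genes recurred between batches. Across 6569 genes measured in both, log2 fold changes correlated at r = 0.828 (rho = 0.75) for INTS11 and r = 0.908 (rho = 0.863) for N211del, across genes, which are not independent replicates. At 1.5-fold or more, 409 genes rose and 34 fell in both batches for INTS11, where 59.8 and 0.854 would overlap by chance, and 998 rose and 58 fell for N211del, where chance gives 238 and 1.55. INTS8 and N211del correlated at r = 0.903 in batch 1, INTS11 and INTS8 at r = 0.723 and INTS11 and N211del at r = 0.624 (rho = 0.85, 0.678 and 0.614). In batch 2 INTS11 and N211del correlated at r = 0.501 (rho = 0.465).

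**Figure D2:**
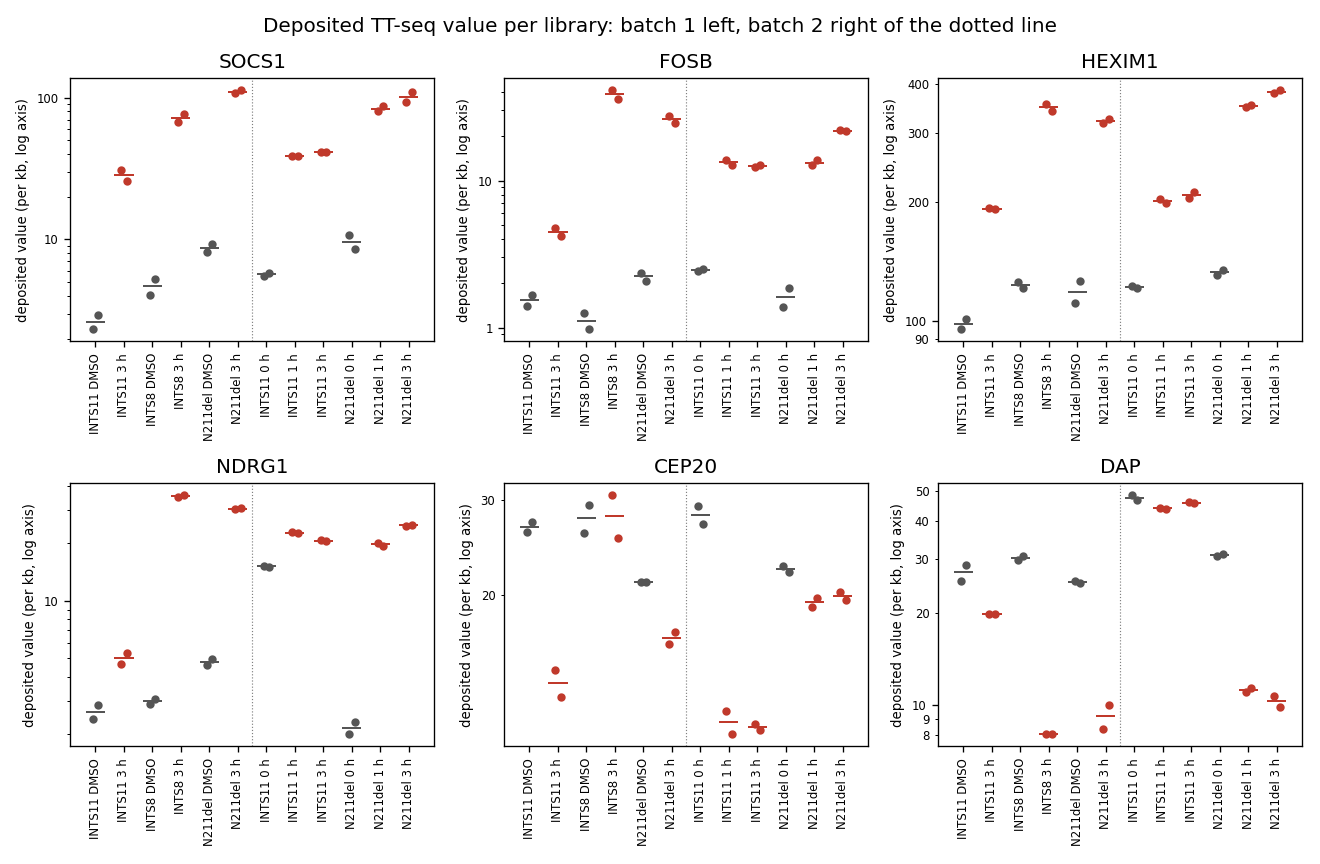
Points are the deposited values per kilobase of 6 genes in each library, on log axes, with controls (DMSO or 0 h) in grey, dTAG13 in red and a line at the mean of each pair of libraries. HEXIM1 is higher with dTAG13 in every line and batch (349 ± 9.95 against 123 ± 3.12 in the INTS8 line), and CEP20 is lower in the INTS11 line (11.4 ± 0.221 against 28.2, 3 h and 0 h in batch 2).

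FOSB, SOCS1 and HEXIM1 were higher at 1 h than at 0 h in both lines, with no vehicle group beside them. FOSB at 1 h stood at 13.3 ± 0.668 in the INTS11 line (n = 2; log2 fold change against 0 h 2.39 ± 0.11, adjusted p = 6.73e-07) and 13.2 ± 0.719 in the N211del line (2.97 ± 0.11, adjusted p = 2.52e-08). SOCS1 rose by 2.74 and 3.12, HEXIM1 by 0.73 and 1.41 (log2 fold changes in the INTS11 and N211del lines). CEP20 in the INTS11 line had fallen by 1 h (log2 fold change −1.27 ± 0.05, adjusted p = 5.11e-07), and so had DAP in the N211del line (−1.45 ± 0.04, adjusted p = 8.5e-09). Between 1 and 3 h in the N211del line TMEM45B fell further (log2 fold change −1.29 ± 0.07, adjusted p = 2.06e-05), as did PRR15L (−1.27 ± 0.06, adjusted p = 6.35e-06), while FOSB rose (0.73 ± 0.11, adjusted p = 0.00143) and so did the chemokine gene CXCL2 (0.56 ± 0.04, adjusted p = 0.00011).

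The median gene moved by a log2 fold change of 0.16 at 1 h in the INTS11 line and 0.31 in the N211del line, and by −0.13 between 1 and 3 h in the latter. At 1 h camera did not call immediate early genes in either line. Of 31 members 17 were higher and 5 lower in the INTS11 line (19 and 5 adjusted over the list alone; 11 and 7 with centring; camera adjusted p = 0.602). In the N211del line 21 were higher and 5 lower (21 and 5 adjusted over the list alone; 15 and 10 with centring; camera adjusted p = 0.996). They lay 0.25 above the median gene between 1 and 3 h in the N211del line, with 14 of 31 higher and 1 lower (15 and 1 adjusted over the list alone). The camera adjusted p was 9.62e-20, and adjusted p = 0.081 with an estimated correlation. Fold changes between 1 and 3 h ran with gene length (rho = −0.213 in the N211del line and −0.437 in the INTS11 line). In the N211del line the medians were −0.07 in the shortest of 4 bins and −0.16 in the longest. At 1 h 3882 genes differed from 0 h in the INTS11 line, 3197 higher and 685 lower (2016 and 2108 with centring). Lower genes there numbered 442 without 0 h replicate 1 and 425 with pairs averaged. In the N211del line 4932 differed, 4590 higher and 342 lower (2049 and 2509 with centring). The 1 h and 3 h comparisons share their 0 h libraries, and r was 0.932 for INTS11 and 0.908 for N211del. Unchanged groups and their 0 h controls, both simulated as independent noise with the fitted spread, gave 0.502 and 0.503. The covariances were 0.203 and 0.256 against a simulated 0.011 in both lines. This noise holds no difference of the 0 h group beyond its replicate spread. Both times would share such a difference, so it is not excluded. At 1.5-fold or more 762 genes rose and 28 fell at both times in the INTS11 line, and 1237 and 28 in the N211del line. Independent lists would share 124 and 0.321, and 338 and 0.486. The simulated unchanged groups shared 0.03 and 0.02 calls of any size on average, and at most 1. Between 1 and 3 h 2583 genes differed in the N211del line, 153 higher and 2430 lower (803 and 530 with centring), with 1527, 1540 and 1391 without 1 h replicate 1, 1 h replicate 2 or 3 h replicate 2, and 1011 with pairs averaged. Higher genes there numbered 84 without 3 h replicate 1. In the INTS11 line 1083 differed, 33 higher and 1050 lower (108 and 84 with centring), but 1 did without 1 h replicate 1, 1 without 3 h replicate 1 and 3 without 3 h replicate 2. With pairs averaged limma called 0 there (1402 at an unadjusted p under 0.05), and voom without averaging called 2157.

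The responses of the lines were compared directly as differences of log2 fold changes. In batch 1 FOSB rose less in the INTS11 line than in the INTS8 line (difference −3.52 ± 0.18, adjusted p = 1.44e-11), as did NDRG1 (−2.62 ± 0.14, adjusted p = 1.44e-11), while PRR15L and TMEM45B fell less (1.82 ± 0.11, adjusted p = 6.24e-11, and 2.34 ± 0.22, adjusted p = 3.37e-06). CEP20 and LIN9 were lower in the INTS11 response than in the INTS8 response (differences −0.97 ± 0.13, adjusted p = 4.49e-06, and −1.41 ± 0.11, adjusted p = 5.12e-09). Against the N211del response, the INTS11 response was lower for FOSB in both batches (differences −2.01 and −1.40) and for NDRG1 (−1.75 and −3.02), and higher for DAP (1.00 and 1.53). E2F2 was higher in the INTS11 response in both batches (differences 0.41 and 0.67), and the replication helicase gene MCM5 in batch 2 (0.50), with 0.21 in batch 1 (adjusted p = 0.116). Immediate early genes differed between the INTS11 and INTS8 responses with 20 of 29 lower (23 adjusted over the list alone; camera adjusted p = 8.59e-09, and adjusted p = 0.739 with an estimated correlation). S phase genes differed between INTS11 and N211del in batch 2, with 12 of 20 higher and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.000241, and adjusted p = 0.981 with an estimated correlation). In batch 1 they were not called, with 1 higher and 3 lower (1 and 2 adjusted over the list alone; 9 higher with centring; camera adjusted p = 0.211).

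Between INTS8 and N211del, FOSB (difference 1.51 ± 0.18, adjusted p = 0.000114), NR4A2 (0.86 ± 0.12, adjusted p = 0.000198) and NDRG1 (0.88 ± 0.14, adjusted p = 0.000896) rose more in the INTS8 line, and PRR15L fell more (−0.80 ± 0.11, adjusted p = 0.000187). HEXIM1 had a difference of 0.06 ± 0.09 (adjusted p = 0.677). The median gene's difference was −0.16 here (−0.24 and −0.08 without N211del dTAG13 replicate 1 or 2), −0.26 for INTS11 against N211del in batch 1 and −0.11 in batch 2. Genes that differed numbered 3190 for INTS11 against N211del in batch 1, 316 higher and 2874 lower (1237 and 992 with centring; 181 and 1155 with pairs averaged), and 3540 in batch 2, 1053 higher and 2487 lower (1993 and 1752 with centring; 599 and 1643 with pairs averaged). For INTS11 against INTS8 1673 differed, 395 higher and 1278 lower (1373 and 1125 with centring; 179 and 715 with pairs averaged). For INTS8 against N211del 727 differed, 132 higher and 595 lower (469 and 287 with centring), a count that rests on single libraries. Higher genes numbered 82 without INTS8 dTAG13 replicate 1. The total was 307 and 224 without INTS8 DMSO replicate 1 or 2, 181 without INTS8 dTAG13 replicate 2, 289 and 229 without N211del DMSO replicate 1 or 2, and 2522 and 268 without N211del dTAG13 replicate 1 or 2. Voom gave 1367, and averaged pairs gave 72.

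In DMSO the N211del line already differed from the INTS8 line. DDIT4, a stress-induced inhibitor of mTORC1 signalling, stood at 377 ± 27.8 against 133 ± 11.4 (n = 2; 2.84-fold, adjusted p = 2.73e-09), and EGR1 at 147 ± 8.32 against 70.1 ± 14.1 (log2 difference 1.08 ± 0.13, adjusted p = 7.92e-05). FOSB, SOCS1 and the stress gene SESN2 were higher by 0.95, 0.90 and 0.66 (log2 differences), and NABP1 was lower (−0.63 ± 0.06). The median gene was lower in the N211del line by a log2 difference of −0.30. Relative to it immediate early genes lay 0.81 higher, with 24 of 29 higher and 2 lower (24 and 2 adjusted over the list alone), and NF-kB target genes 0.70 higher, with 9 of 13 higher and 2 lower (9 and 2 adjusted over the list alone; 11 higher with centring). Both were called by camera with a preset correlation (adjusted p = 6.04e-28 and 2.67e-10) and with an estimated one (adjusted p = 0.0427 for both). The difference ran with gene length (rho = −0.541), from a median of −0.03 in the shortest of 4 bins to −0.46 in the longest. With each library corrected for length the lists lay 0.49 and 0.38 higher, with 13 members higher and 6 lower, and 3 higher and 2 lower. Both then lost their call (adjusted p = 0.239 and adjusted p = 0.431 with an estimated correlation). With libraries centred as well these were 0.127 and 0.0495 (adjusted p, limma), with 21 immediate early genes higher and 3 lower and 11 NF-kB targets higher. In total 4190 genes differed, 331 higher and 3859 lower, against 1727 and 1732 with each library centred on its median, and 189 and 2522 with pairs averaged.

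Genes of low level rose most. With genes split into 4 bins of equal size by mean level, the lowest bin had median log2 fold changes after 3 h of 0.24 and 0.39 in the INTS11 line (batch 1 and batch 2), 0.34 in the INTS8 line, and 0.43 and 0.45 in the N211del line. The highest bin had −0.12 and 0.02, −0.06, and 0.11 and 0.07. Across genes fold changes ran with level in each of these comparisons (rho from −0.38 to −0.251). The list tests above were not corrected for level.

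**Figure D3:**
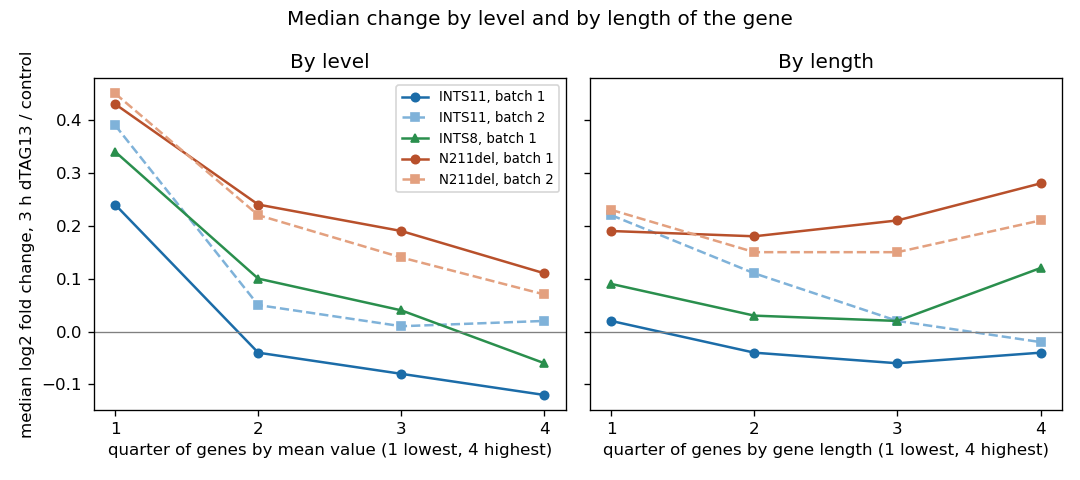
Median log2 fold change (3 h dTAG13 over control, vertical axis) of genes in 4 bins of equal size by mean level (left) and by gene length (right), with 1 line for each of the 5 comparisons. The lowest bin by level has the highest median in each comparison, 0.24 to 0.45.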

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

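The 4 response differences were planned; all tests of explanations in this part were chosen after the result was seen. The comparisons of responses between lines were singled out because the test of the difference itself called genes: 3190 for INTS11 against N211del in batch 1, 3540 for the same pair in batch 2, and 1673 for INTS11 against INTS8. For INTS8 against N211del the count was 727, and it was 307 and 224 without INTS8 DMSO replicate 1 or 2, 181 without INTS8 dTAG13 replicate 2, 289 and 229 without N211del DMSO replicate 1 or 2, and 2522 and 268 without N211del dTAG13 replicate 1 or 2.

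Among 29 immediate early genes 7, NR4A2 among them, rose more in the INTS8 line than in the N211del line (8 higher and 1 lower adjusted over the list alone; limma's camera adjusted p = 1.14e-10, and adjusted p = 0.708 with an estimated correlation). A shift of all genes does not account for these genes, since the median difference of all genes had the opposite sign (−0.16), also without N211del dTAG13 replicate 1 or 2 (−0.24 and −0.08), though its size rests on those libraries. With each library corrected for gene length, 8 members still differed (7 higher and 1 lower), so length alone does not account for those members. The list then lay 0.25 above the median gene, against 0.34 without the correction (camera adjusted p = 3.66e-07, and adjusted p = 0.987 with an estimated correlation). Large changes of single members would remain whether or not length moved the list, so this does not decide for the list as a whole. The list already lay 0.81 higher in the N211del line in DMSO (0.49 with the length correction), and with dTAG13 it was still 0.41 higher there, with 15 members higher and 4 lower. The INTS8 line was not in batch 2, so recurrence was not checked, and an effect of the N211del variant stays open, untested.

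The DMSO libraries of the N211del and INTS11 lines differed in batch 1, with a log2 gap of −0.53 between the longest and shortest of 4 length bins (0.12 in the widest replicate pair). This difference correlated across genes at −0.0086 with the 0 h difference in batch 2, where the length gap was 0.02. That argues against a lasting property of the lines as the source of the whole difference. A lasting part beneath the batch 1 length trend (rho = −0.451) is not excluded, since no correlation corrected for length was made. For genes at least 1.5-fold higher in the N211del line a lasting property cannot be told apart from genes that vary more. Of these, 136 were higher in both batches (2.05 times the 66.2 by chance), while 216 genes went opposite ways (152 by chance). Genes at least 1.5-fold lower in that line in both batches numbered 74, where chance gives 86.6. A test of drift with length was dropped after its value was seen, since pairs that may be technical do not show drift between groups. Handling of each group as a unit and the line's state on that day are confounded with line and stay open, untested.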

How the results depend on the processing

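Voom, averaged pairs and the length correction were chosen after the result was seen; the other alternatives were planned. Counts of differing genes stayed within 1.5 times under both pseudocounts and both filters for 14 of 14 contrasts. Replicate numbers did not pair the samples (r of replicate differences −0.102 to 0.068), and the replicate block left 14 of 14 counts within 1.5 times. Centring moved the 3 h against 1 h counts, to 192 for INTS11 and 1333 for N211del. Only the named libraries gave 1 gene for INTS11 3 h against 1 h. Both batches in 1 fit gave 3952 for the mean INTS11 response of the 2 batches, a different comparison from the 2575 of batch 1 alone. Voom gave 2157 for INTS11 3 h against 1 h and 1367 for INTS8 against N211del. Averaged pairs gave 1374 for INTS11 in batch 1, 2265 for INTS11 in batch 2, 1011 for N211del 3 h against 1 h, 1336 and 2242 for INTS11 against N211del in batch 1 and batch 2, 72 for INTS8 against N211del, 894 for INTS11 against INTS8 and 2711 for the DMSO lines. They gave 0 for INTS11 3 h against 1 h with limma (1402 genes at an unadjusted p under 0.05; voom without averaging gave 2157). Averaging leaves fewer samples, and the cause of the other moves was not tested. Among genes called in both batches the correlations were 0.922 for INTS11 and 0.936 for N211del, but choosing genes by their calls raises r by itself.

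With 1 library left out the counts ranged from 1686 to 2033 for INTS11 in batch 1, 2971 to 3160 for INTS8, 2930 to 4071 for N211del in batch 1, 3176 to 3601 and 3021 to 3390 for INTS11 at 1 and 3 h, 4382 to 4701 and 3755 to 4032 for N211del at 1 and 3 h, 1 to 949 and 1391 to 1764 for 3 h against 1 h in INTS11 and N211del, 2422 to 4014 and 2970 to 3376 for INTS11 against N211del in batch 1 and batch 2, 181 to 2522 for INTS8 against N211del, 1294 to 1563 for INTS11 against INTS8 and 3571 to 3825 for the DMSO lines. Libraries that moved a count by over 1.5 times were INTS11 dTAG13 replicate 2 in batch 1 (1686), INTS11 1 h replicate 1 (1), 3 h replicate 1 (1) and 3 h replicate 2 (3), N211del 1 h replicates 1 and 2 (1527 and 1540) and 3 h replicate 2 (1391), and for INTS8 against N211del, INTS8 DMSO replicates 1 and 2 (307 and 224), INTS8 dTAG13 replicate 2 (181), N211del DMSO replicates 1 and 2 (289 and 229) and N211del dTAG13 replicates 1 and 2 (2522 and 268). The cause was not tested.

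Of 3903 values of named genes, 3777 kept direction and call, 120 lost the call and 6 turned direction. The 6 were in N211del batch 1 with centring, at log2 fold changes of −0.06 for PPP2CB, −0.07 for PSMD2, 0 for CLK1, −0.01 for RRP12, −0.05 for UBTF and −0.02 for CDH17. Of 77 list results, 75 lost their call with an estimated correlation, 2 with centring, 3 with the filter at a mean of 1 and 1 with the replicate block. The length correction left 6 of 7 called with a preset correlation. In simulation 40% of the smallest changes made were recovered in the INTS11 contrast of batch 1.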

Other observations

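The overlap counts below were not planned, and the tests on level were chosen after the result was seen. Across the 5 main comparisons 246 of 6569 genes rose by at least 1.5-fold in each, where the product of the shares gives 0.371. That product takes the comparisons as independent. They are not, since the INTS11 and N211del lines were each measured in both batches, so it is too low for a chance level. Among the 246, the antiviral gene MX1 rose by log2 fold changes of 1.51 and 1.41 in the INTS11 line (batch 1 and batch 2). It rose by 1.17 in the INTS8 line and by 0.81 and 0.72 in the N211del line. SOCS1 rose by 3.38 and 2.84, 3.93, and 3.64 and 3.39. The 4 genes lower in each, named after their values were seen, were CLYBL, LDAH, NUCKS1 and VPS41; the vesicle trafficking gene VPS41 changed by −0.68 and −0.59, −1.11, and −0.87 and −0.75, and the chromatin gene NUCKS1 by −0.65 and −0.63, −1.18, and −0.93 and −0.70.

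The INTS11 and N211del lines went opposite ways for fewer genes than independent responses would give, which is the chance level used here. Their fold changes correlated (r = 0.624 in batch 1 and r = 0.501 in batch 2), so this shortfall is no separate result. In both batches 78 genes were lower in the INTS11 line and higher in the N211del line (328 by chance) and 8 the reverse (61.2 by chance), by calls of any size. With each library centred on its median the counts were 22 and 51 (278 and 365 by chance). At 1.5-fold 1 gene, the sulfotransferase SULT1C3, named after its values were seen, was higher in the INTS11 line (log2 fold changes 0.63 and 0.69) and lower in the N211del line (−1.28 and −0.76).

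Genes of low level rose most after dTAG13. Setting 4 bins of level by the other batch left a gap of at least 0.29 (log2) between lowest and highest bin in each of 4 comparisons, which argues against selection by the same libraries. An equal background per kilobase in treated libraries would give all low genes the same added value. The additions ranked alike between batches (rho 0.66 for INTS11 and 0.871 for N211del over 1643 genes), so they held parts that differed by gene. An equal background on top of such parts would leave the ranks unchanged, so this does not decide whether one was present. Background that differs by gene, and read-in from neighbouring genes, may also remain and were not tested. A release of low genes by loss of Integrator is a hypothesis only.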
